A study of Mus musculus with 2 samples.

How the data were processed

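The study measured single-cell RNA from the femur fracture callus of 24-month-old male mice, taken 10 days after a stabilised fracture. A hydrogel placed at the fracture held either PBS or an antibody against CSF1 (2 µg, where CSF1 is the growth factor that macrophages and osteoclasts need) together with the bone morphogenetic protein BMP2 (5 µg). Each of the 2 libraries pooled 3 mice, per the labels, so each group had 1 library and the animals within a pool could not be told apart. Cells had been sorted as negative for propidium iodide and for the red-cell marker Ter119, and libraries were made with the 10x Genomics 3′ chemistry, per the labels' protocols.

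The deposited values are raw UMI counts per gene and barcode, given as sparse matrices, and Cell Ranger is named in the submitters' processing notes. The genome build and the annotation are not given in the sources used here, so no coordinates are printed. The files pair gene identifiers with symbols. Of 54752 identifiers, 53861 matched GENCODE M21 with their version and 54723 without it. Where a symbol stood for several identifiers, the first listed kept the plain symbol.

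Each matrix held exactly 10000 barcodes, and none was shallow, so the lists look capped. With free RNA in every droplet, an unknown number of these barcodes may hold no cell. Shares and class sizes below are therefore of barcodes, and a cell call from all droplets was not made here. Barcodes needed at least 500 UMIs, at least 250 genes and at most 10% mitochondrial UMIs. The UMI and gene minimums removed none, because the smallest barcode held 3325 UMIs in the PBS library and 4444 in the treated library. The mitochondrial limit removed 557 and 924 barcodes. Scrublet (expected rate 0.08, run through scanpy 1.11.5) called 1 barcode a doublet in the PBS library and 0 in the treated library. That is under 0.5%, so the fallback fixed beforehand was used, and the 5% of barcodes with the highest doublet score were removed (472 and 454). This left 8971 and 8622 barcodes.

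Both libraries were clustered together without batch correction: log counts per 10000, 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 (igraph 0.11.9). A cluster took the name of the marker class with the most markers at 1.5-fold or more over the other barcodes of the same library, with at least 3 such markers. It stayed unnamed when its top 10 genes held more markers of another class, the skeletal classes being counted as 1. The markers were fixed before the data were examined, and the 1.5-fold scoring rule was chosen after seeing the data. The class called skeletal stromal joined stromal, chondrocyte, osteoblast and tenocyte clusters, and the class called mononuclear phagocyte joined monocyte, macrophage, osteoclast and dendritic clusters. Clusters below the naming rule are given by number. 3 genes of the fixed lists and markers (Ahsp, Ccn2 and Atp6v0a3) were not among the symbols of the files.

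With 1 library per group there was no test and no p-value. Shares carry exact Clopper-Pearson 95% intervals. UMIs were summed per library and class and given as CPM of the class total, with exact Poisson intervals, and the ratio of treated to PBS carries an exact conditional binomial interval. All these intervals cover counting error only. A class was compared when it held at least 100 barcodes in each library. For each of the fixed gene lists, the median of log2(CPM + 1), treated minus PBS, was taken over members with at least 10 UMIs. Its percentile among 10000 random lists matched on mean expression in 20 bins describes these libraries and tests nothing. The interval given with a list median comes from the order statistics of its members.

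Named genes followed a rule set before the data were examined. Genes of at least 50 CPM in the higher library were ranked by the bound of the ratio's interval nearest to 1, and the 12 highest and 12 lowest were taken in the skeletal stromal and mononuclear phagocyte classes, and the 6 highest and 6 lowest in the endothelial class. Mitochondrial, ribosomal protein, haemoglobin and immunoglobulin genes, gene models and Xist were left out. Csf1, Csf1r, Bmp2 and Id1 were named in each class compared. Examples from a list come from its 2 members with the most UMIs and its 2 with the largest nearest bound, and not all of these are printed. Which of them to print was decided after their values and alternatives had been seen, and the choice favours genes that kept their direction. Of 176 gene results the rule named, 61 were not chosen for printing, of which Col10a1 in the skeletal class is given below all the same. The list medians taken as the main results were likewise chosen after the values had been seen. The test of dissociation stress was tried in 3 forms, all written after the values were seen. The list median in the stromal-like clusters (0.50) argued against stress, the largest excess over the stress median in the other 3 pairs (0.05) favoured stress, and the count over all 4 pairs (2), which is reported, left it open. The count was kept because it needs no bound chosen from the data.

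Counts were simulated as Poisson draws around the PBS profile of a class, without variation between barcodes, clusters or mice. The intervals assume such draws, so their coverage checks the computation and not whether the real counts behave this way. For the skeletal stromal class, 96.2% of intervals covered the ratio among 17620 unchanged genes. Of the 68 genes changed by 1.5-fold, 100% were placed on the right side of 1. For the mononuclear phagocyte class these values were 96.4% of 9907 genes and 73.5% of 68 genes. Of 100 random lists per class, 7% and 9% fell outside the percentiles 5 to 95.

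Depth limits precision through the number of barcodes and through free RNA, the RNA released from broken cells that enters every droplet. For each class, its level of a gene is therefore set beside the level in other barcodes of the same library. For the mononuclear phagocyte, endothelial and mural classes, a free RNA profile from the 2000 shallowest barcodes of each library, scaled to the chondrocyte markers found in the class, was also subtracted. Values below 0 were set to 0. Even the shallowest PBS barcode held 3325 UMIs, so the profile may include RNA of cells. The subtraction, the skeletal comparisons over other sets of barcodes, the 2000 deepest barcodes and a denominator without 2 clusters were alternatives chosen after seeing the data. Other alternatives covered the filters, doublets, clustering, denominator, scaling, cluster weights, depth per barcode, pseudocount and minimum UMIs per member. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0.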

Results

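The data were UMI counts from 2 single-cell libraries of fracture callus, the repair tissue that bridges a broken bone, from aged mice. 1 library came from 3 mice given PBS in the hydrogel, and the other from 3 mice given anti-CSF1 and BMP2. The PBS library held 46922782 UMIs in 10000 barcodes, with a median of 4143 UMIs per barcode. The treated library held 79447427 UMIs in 10000 barcodes, with a median of 5891. There are no replicate libraries, so no difference below has a replicate check. Intervals of shares, levels and ratios cover counting error only, and those of list medians show the spread among members.

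Cartilage transcripts were found in every barcode of both libraries. Col2a1, which encodes the main cartilage collagen, had a UMI in 100% of barcodes, and its median was 123 UMIs in the 2000 shallowest PBS barcodes and 181 in the shallowest treated ones. Endothelial-like barcodes, which should lack it, held Col2a1 at 31967 CPM in the PBS library and 33227 CPM in the treated library, against 43874 and 50901 CPM in all barcodes outside the blood, vessel and muscle clusters. These are called the remaining barcodes here. Neutrophil transcripts filled the PBS library in the same way. S100a8, a calcium-binding protein of neutrophils, had a UMI in 99.9% of PBS barcodes and in 26.6% of treated ones. Each level below is thus partly the level of its library's free RNA.

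**Figure D1:**
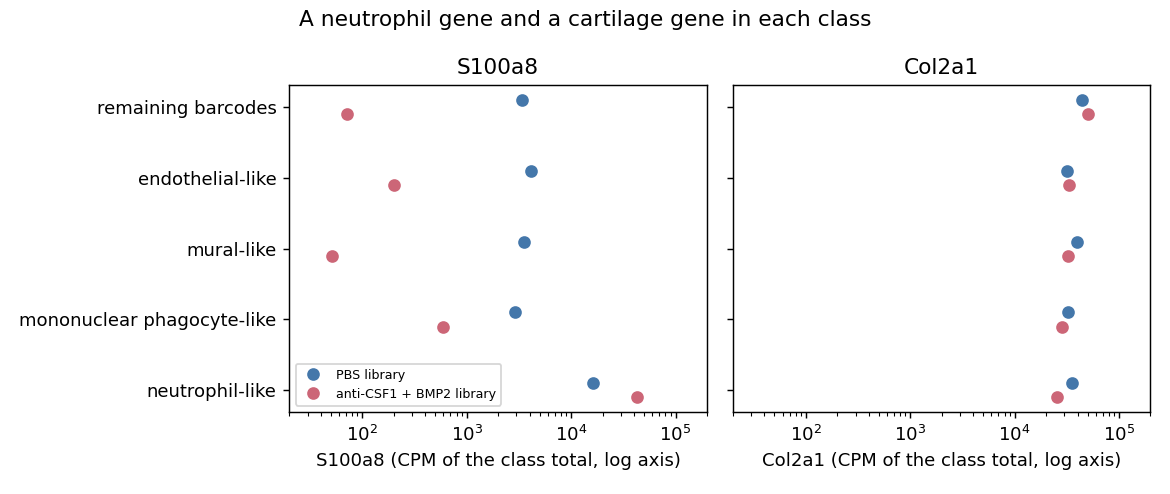
S100a8 and Col2a1 in CPM of the class total (log axes) in the PBS library (blue) and the anti-CSF1 plus BMP2 library (red), 1 point per class and library. Col2a1 lies between 25588 CPM (treated neutrophil-like) and 39159 CPM (PBS mural-like) in the classes shown that should lack it, and S100a8 lies at 3395 CPM in the remaining PBS barcodes against 71.8 CPM in the treated ones.

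The first comparison asked which cell classes the treated callus held. Neutrophil-like barcodes, led by S100a9, S100a8, Camp, Ngp and Retnlg, made up 11.3% of the PBS library (1011 of 8971, interval 10.6 to 11.9%) and 0.383% of the treated library (33 of 8622, interval 0.264 to 0.537%). That is a share 29.4-fold higher in the PBS library (interval 20.8 to 43.0). Over whole libraries, without any clusters, S100a8 stood at 4758 CPM in PBS and 214 CPM in treated barcodes, S100a9 at 7574 and 362 CPM, and Retnlg at 853 and 22.1 CPM. Haemoglobin transcripts, from red cells that the Ter119 sort removes, were also higher in the PBS library, at 2359 against 107 CPM. S100a8 reached 16221 CPM in the neutrophil-like PBS barcodes and 42975 CPM in the treated ones. The neutrophil markers summed to 54911 CPM in the PBS class against 11394 CPM in the remaining PBS barcodes. In the treated library they summed to 152594 against 309 CPM. An unknown part of the 1011 PBS barcodes may thus owe their class to free RNA, so the 2 shares may not count like barcodes. How many PBS barcodes are called neutrophil-like depended on the clustering, from 1011 in the main setting to 6430 of 8971 at Leiden resolution 0.5. The ratio of treated to PBS share stayed below 1 in all alternatives run but ran from 0.00922 at that resolution to 0.141 with each library clustered on its own, where the shares were 16.1% and 2.27%.

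Mononuclear phagocyte-like barcodes, which hold macrophages and related cells, were 2.13% of the PBS library (191 barcodes, interval 1.84 to 2.45%) and 1.38% of the treated library (119 barcodes, interval 1.14 to 1.65%), a ratio of 0.648 (interval 0.511 to 0.819). The cluster was led by Cd74, H2-Aa, Apoe, C1qb, C1qa and Acp5. Its ratio was below 1 in all 10 alternatives, between 0.362 and 0.662. Endothelial-like barcodes, led by Egfl7, Plvap and Pecam1, were 5.14% and 5.95% of the libraries (461 and 513 barcodes), a ratio of 1.16 (interval 1.02 to 1.32) that turned to 0.557 at Leiden resolution 0.5. Mural-like barcodes, the pericytes and smooth muscle cells of vessels, were 3.44% and 2.31% (309 and 199 barcodes), a ratio of 0.670 that lay above 1 in 4 of 10 alternatives. Muscle-like barcodes, led by Ttn, Neb and Myog, were 0.223% and 0.754% (20 and 65 barcodes), a ratio of 3.38 (interval 2.02 to 5.89). This ratio is not stable: no PBS barcode was called muscle-like with at most 20% mitochondrial UMIs, at Leiden resolutions 0.5 and 2.0 or with separate clustering, and with at most 5% mitochondrial UMIs no cluster was.

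Skeletal stromal-like barcodes were 11.02% of the PBS library (989 barcodes) and 48.3% of the treated library (4164 barcodes). Part of this gap lies in which clusters reached the naming rule. Treated cluster 12 is counted in the class. PBS cluster 2 (1939 barcodes), which shared 26 of its top 50 genes with cluster 12, had 1 chondrocyte marker and stayed unnamed. Whether any of the gap lies in the callus itself was not tested. Unnamed clusters held 66.8% of the PBS barcodes (5990) and 40.9% of the treated ones (3529), and 3 of the 5 skeletal clusters came almost wholly from 1 library. With each library clustered on its own, the shares were 34.3% and 36.1%, a ratio of 1.05, but the ratio ran up to 11.8 at Leiden resolution 0.5, and it was 1.79 (9.89% and 17.7%) for the stromal-like clusters 5, 13 and 15 alone. In the PBS library the class was mostly cluster 5 (832 barcodes, led by Aspn, Ptn and Prg4). In the treated library it was mostly cluster 12 (2334 barcodes, led by Nfatc2, Nr4a2 and Col27a1, with 7 chondrocyte markers) and cluster 15 (1418 barcodes, led by Col8a1, Fbn2 and Igfbp5). Clusters 5 and 15 shared 34 of their top 50 genes.

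**Figure D2:**
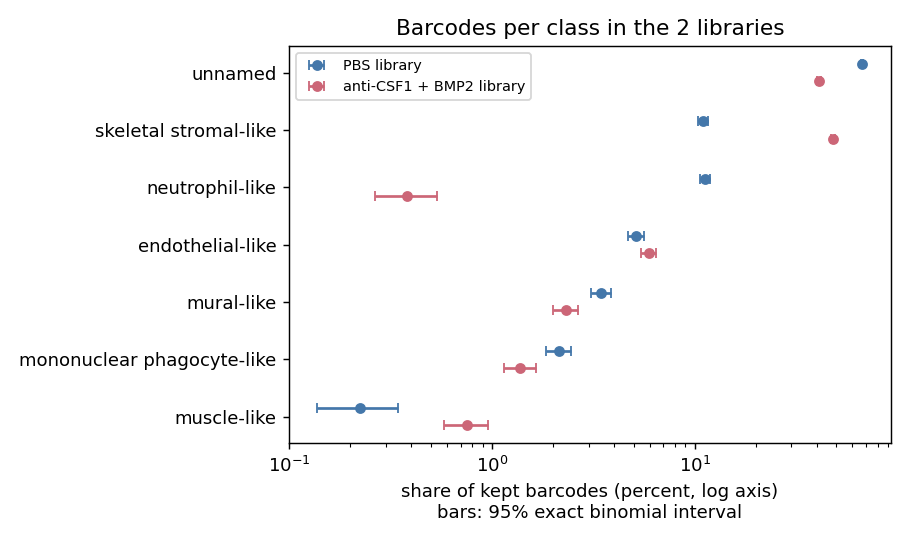
Share of kept barcodes in each class (percent, log axis) in the PBS library (blue, 8971 barcodes) and the treated library (red, 8622 barcodes), with 95% exact binomial intervals. The neutrophil-like class shows 11.3% against 0.383%, and the unnamed class is the largest in the PBS library while the skeletal stromal-like class is the largest in the treated one.

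The second comparison asked how the skeletal cells of the callus differed. Genes that BMP signalling switches on through SMAD proteins were higher in the treated library: 14 of 16 measured members, with a median log2 difference of 0.56 (interval 0.14 to 0.97) at percentile 100 of the random lists. Id1, an inhibitor of differentiation factors, stood at 223 CPM in PBS and 405 CPM in treated skeletal stromal-like barcodes, a ratio of 1.82 (interval 1.71 to 1.93) that was 1.15 with at most 20% mitochondrial UMIs. Smad7, a feedback inhibitor of the pathway, had 118 and 278 CPM (ratio 2.36, interval 2.17 to 2.56, but 1.14 with at most 20% mitochondrial UMIs), Id3 had 320 and 470 CPM (ratio 1.47) and Id4 had 5.58 and 18.4 CPM (ratio 3.30, interval 2.27 to 4.96, but 1.09 with equal weight for clusters 8 and 13). The same list had a median of 0.37 in all remaining barcodes and 0.50 in the stromal-like clusters alone, which are sets of barcodes chosen after seeing the data. In phagocyte-, endothelial- and mural-like barcodes together the same 16 genes had a median of 0.28, with Id1 at 276 and 380 CPM and Smad7 at 153 and 226 CPM. In the PBS library 10 of the 16 were no higher in the skeletal class than in those barcodes, and in the treated library 3 were. Id1 had ratios of 1.25 in mononuclear phagocyte-like, 1.37 in endothelial-like and 1.29 in mural-like barcodes, but also of 1.37 in the remaining barcodes, which held 285 and 390 CPM. With free RNA subtracted, Id1 was at 333 and 469 CPM in endothelial-like barcodes (ratio 1.41). In the PBS phagocyte-like and mural-like barcodes it was at 0 CPM, which means at or below the free RNA estimate. Bmp2 itself had a ratio of 1.14 in the skeletal class and of 0.909 in the remaining barcodes.

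**Figure D3:**
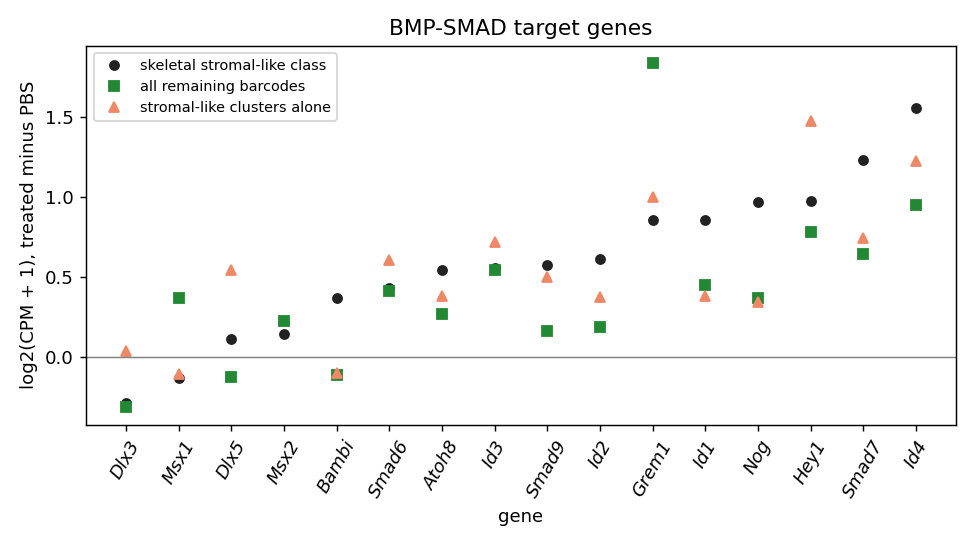
Difference in log2(CPM + 1), treated minus PBS, for the 16 BMP-SMAD target genes in the skeletal stromal-like class (black circles), all remaining barcodes (green squares) and the stromal-like clusters alone (orange triangles). In the skeletal stromal-like class 14 members lie above 0 and 2 below.

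Bone matrix genes differed from one another. The osteogenic list had 10 of 14 measured members higher in the treated library, with a median of 0.32 (interval -0.02 to 0.78, percentile 99.96). Its most abundant member Col1a1 had a ratio of 1.096, which turned in 1 alternative, and Spp1 had a ratio of 0.987. Ibsp, the bone sialoprotein that nucleates mineral, had 5462 and 12340 CPM (ratio 2.26, interval 2.23 to 2.29), with a ratio of 1.83 in the remaining barcodes and 2.46 in the stromal-like clusters. The phagocyte-, endothelial- and mural-like barcodes together held it at 8074 and 7661 CPM, above the skeletal class in the PBS library and below it in the treated one. Endothelial-like barcodes alone, however, held 4061 and 7854 CPM (ratio 1.93). With free RNA subtracted they held 0 CPM in both libraries, a level at or below the free RNA estimate. A rise of about this size was thus not particular to skeletal barcodes, and free RNA may account for part of it. Ifitm5, a membrane protein of osteoblasts, had 2.69 and 13.1 CPM (ratio 4.85, interval 2.87 to 8.95), and Col1a2, a chain of type I collagen, had a ratio of 1.34. Alpl, the alkaline phosphatase of mineralising cells, had 594 and 1021 CPM (ratio 1.72). Over the alternatives run, the lowest ratios were 1.43 for Ibsp, 1.85 for Ifitm5 and 1.05 for Alpl. The chondrogenic list was higher in 14 of 15 members in the class as defined (median 0.50), but its median was 0.03 in the remaining barcodes and -0.17 in the stromal-like clusters. Col2a1 went with it, with ratios of 2.05, 1.16 and 0.961, and Col9a2 with ratios of 1.91, 1.21 and 1.08. In the PBS library 14 of the 15 were no higher in the class than in phagocyte-, endothelial- and mural-like barcodes. The hypertrophic cartilage list had 6 of 9 members higher (median 0.19), but its median was -0.01 in the remaining barcodes and -0.33 with at most 20% mitochondrial UMIs, and it was above 0 in 13 of 18 alternatives. Col10a1, 1 of the list's 2 members with the most UMIs, was lower, with 2900 and 2161 CPM (ratio 0.745). Its ratios were 0.660 in the remaining barcodes and 0.612 in the stromal-like clusters, and it turned in 1 of 16 alternatives.

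The 12 genes highest in treated skeletal stromal-like barcodes were, in the order of the rule, Slpi, Lbp, Nrn1, Ptgs2os, Cxcl1, Nr4a3, Serpina3n, Ibsp, Smad7, Rcan1, Il11 and Car8. Part of this order reflects the clusters in the class. Cluster 12, with 2334 treated and 9 PBS barcodes, had Cxcl1 and Nr4a3 among its top 10 genes. In the stromal-like clusters alone their ratios were 1.49 and 1.21, against 2.93 for Slpi and 2.495 for Lbp. Slpi, an inhibitor of leukocyte proteases, had 168 and 592 CPM (ratio 3.54, interval 3.31 to 3.79), and Lbp, the lipopolysaccharide-binding protein, had 88.0 and 294 CPM (ratio 3.34, interval 3.05 to 3.68). The neutrophil attractant Cxcl1 had 50.05 and 142 CPM (ratio 2.84), Serpina3n had a ratio of 2.93, and the cytokine Il11 had 80.3 and 188 CPM (ratio 2.34). Over the alternatives the last 3 went down to 1.35, 1.16 and 1.35. Phagocyte-, endothelial- and mural-like barcodes held 167 and 376 CPM of Slpi, 114 and 222 CPM of Lbp and 56.1 and 90.2 CPM of Cxcl1, so the PBS levels were at background. Slpi and Lbp were also 3.18- and 2.26-fold higher in the remaining barcodes, while Nr4a3 had ratios of 0.960 and 0.921 under the other mitochondrial limits. The dissociation-stress list moved with these genes: all 12 members were higher (median 0.57, percentile 100), with a median of 0.09 at most 5% mitochondrial UMIs, including Fos (ratio 1.46) and Jun (ratio 1.43). With equal weight for clusters 8 and 13, the ratio of Fos was 0.858.

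The 12 genes lowest in treated skeletal stromal-like barcodes were Retnlg, Ifitm6, S100a9, S100a8, Wfdc21, Il1b, Slc4a1, Lilr4b, Acod1, Ltf, Ngp and Cd52. Among the fixed markers, Retnlg, S100a9, S100a8, Ltf and Ngp stand for neutrophils, Slc4a1 for red cells and Ifitm6 for monocytes. In the PBS library none stood clear of the other classes: S100a8 had 2846 CPM in skeletal stromal-like barcodes and 3658 CPM in phagocyte-, endothelial- and mural-like barcodes together. The inflammatory secreted factors had 10 of 15 members lower (median -2.46, interval -3.63 to 0.60, percentile 0). The median turned to 0.11 with at most 5% mitochondrial UMIs and to 0.535 with equal weight for clusters 8 and 13, and 11 of the 15 were no higher in the PBS class than in the other classes. Il1b, with 143 and 2.66 CPM, stood at 158 CPM in the other PBS classes. Cxcl5, a neutrophil attractant, had 38.3 CPM in PBS and 0.316 CPM in treated skeletal barcodes (ratio 0.00825, interval 0.00419 to 0.0147) and only 1.10 CPM in the other PBS classes, but its ratio was 0.975 and 0.6795 with at most 5% and 20% mitochondrial UMIs. Ptgs2, which makes prostaglandins, and Cxcl1 went the other way, with ratios of 1.52 and 2.84.

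Interferon-response genes were lower in the treated library, in 12 of 12 measured members (median -1.59, interval -3.24 to -0.54, percentile 0), and the median was negative in all 18 alternatives, at its weakest -0.41 with equal weight for clusters 8 and 13. There the ratios of Ifit1 and Isg15 were 0.682 and 0.777. Ifit1 had 42.2 CPM in PBS skeletal barcodes and 1.32 CPM in treated ones (ratio 0.0312, interval 0.0225 to 0.0426), against 11 CPM in the other PBS classes. Isg15 had 42.4 and 7.34 CPM (ratio 0.173). Rsad2 had 29.5 and 0.526 CPM, but also 29.5 CPM in the other PBS classes. Of the 12 interferon members, 6 were no higher in the PBS skeletal class than in the other PBS classes, and 11 in the treated library. Proliferation genes were lower in 16 of 16 members (median -0.62, percentile 0). Of these, 11 were no higher in the PBS skeletal class than in the other PBS classes, and all 16 in the treated library. Mki67 had 59.5 and 27.3 CPM and Ube2c 26.6 and 11.3 CPM, while the other PBS classes held them at 74.1 and 34.3 CPM. With equal weight for clusters 8 and 13 their ratios were 1.07 and 1.10. Cluster 13 was led by mitosis genes. This setting gives it the same weight in both libraries, which hides any difference in its share. The median was -0.56 in the remaining barcodes, -0.52 in all kept barcodes and -0.16 in the stromal-like clusters. It was -0.00727 with each library clustered on its own, and below 0 in all 18 alternatives.

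The other skeletal lists had medians that were smaller or turned with the set of barcodes. The class as defined and the remaining barcodes gave -0.37 and 0.20 for stromal progenitor genes, 0.08 and 0.41 for adipogenic genes, and -0.48 and 0.14 for osteoclast-regulating factors. Senescence genes had -0.01 and 0.14, matrix-remodelling enzymes -0.12 and 0.38, TGF-beta and fibrosis genes -0.17 and 0.29, and glycolysis and hypoxia genes -0.09 and 0.01. Many members that the rule for named genes picked in these lists, among them Tagln, Acta2, Fabp4, Prrx1 and Ly6a, changed direction with the processing and are given no value here. Mmp12, a macrophage elastase, had 11.7 and 0.0790 CPM (ratio 0.00673, interval 0.00135 to 0.0206, but 0.243 with at most 20% mitochondrial UMIs). Mmp3, stromelysin, had 1.54 and 12.2 CPM (ratio 7.93, interval 3.99 to 18.5, but 1.73 with equal weight for clusters 8 and 13). Phagocyte-, endothelial- and mural-like barcodes held Mmp3 at 0.440 and 17.9 CPM, so the treated skeletal level lay below background. Csf1, the factor the antibody binds, had 29.5 and 21.4 CPM in the skeletal class (ratio 0.728), but ratios of 1.198 in the remaining barcodes and 1.49 in the stromal-like clusters. Its receptor gene Csf1r was at 3.08 and 1.05 CPM there.

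The third comparison looked at the cells that CSF1 maintains. In mononuclear phagocyte-like barcodes, all 7 MHC class II genes, which present antigen, were higher in the treated library (median 1.69, interval 0.74 to 1.93, percentile 100). Cd74, the invariant chain, had 1137 and 4327 CPM (ratio 3.81, interval 3.56 to 4.08), H2-Ab1 had 546 and 1866 CPM (ratio 3.42) and H2-Aa had 516 and 1669 CPM (ratio 3.24). The complement genes of tissue macrophages were lower: C1qa with 302 and 137 CPM (ratio 0.454, interval 0.363 to 0.563), C1qb with 392 and 118 CPM (ratio 0.302, interval 0.241 to 0.377) and C1qc with 213 and 60.4 CPM (ratio 0.284). In the remaining barcodes of both libraries C1qa, C1qb and C1qc were below 2 CPM. Over the alternatives the ratio of C1qa stayed below 1 but ran from 0.0229 to 0.555. The free RNA share of the class was estimated at 84.6% in PBS and 70.7% in treated barcodes, and with it subtracted the ratios were 2.45 for Cd74 and 0.188 for C1qb. The higher MHC class II level was not shared by all barcodes. The summed ratio was 0.762 in those with at least 2 C1q UMIs and 6.14 in the others, a split that uses genes of the pattern itself.

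**Figure D4:**
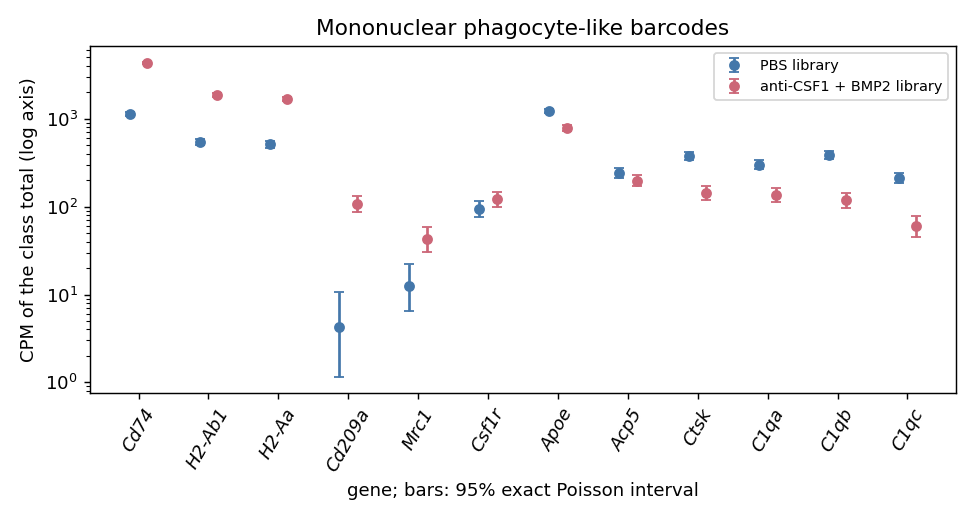
CPM of the class total (log axis) for 12 genes in mononuclear phagocyte-like barcodes of the PBS library (blue, 191 barcodes) and the treated library (red, 119 barcodes), with 95% exact Poisson intervals. Cd74, H2-Ab1, H2-Aa and Cd209a are higher in the treated library, and C1qa, C1qb, C1qc and Ctsk are lower.

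The list of CSF1-receptor and macrophage identity genes was split, with 7 of 13 measured members lower, 6 higher and a median of -0.41 (interval -1.15 to 0.43, percentile 0.02). The lower members include C1qa, C1qb and C1qc, so the median partly repeats the pattern above. Csf1r, the CSF1 receptor, had 94.9 and 122 CPM (ratio 1.28, interval 0.962 to 1.72), and 0.813 with free RNA subtracted. Osteoclast genes had 7 of 12 members lower (median -0.23). Ctsk, the protease of bone resorption, had 380 and 142 CPM (ratio 0.374, interval 0.303 to 0.460), and Acp5, tartrate-resistant acid phosphatase, had 241 and 198 CPM (ratio 0.821, from 0.191 to 1.28 over the alternatives). Monocyte genes (median -0.45, 9 of 11 lower), lipid-associated macrophage genes (median -0.16, 8 of 12 lower) and repair macrophage genes (median 0.30, 6 of 9 higher) went apart. The monocyte median turned to 0.01203 with free RNA subtracted, and the repair macrophage median to -0.11 in the 2000 deepest barcodes. Apoe, a lipid carrier, had 1223 and 791 CPM (ratio 0.647, but 1.85 in the 2000 deepest barcodes of each library), Lpl, lipoprotein lipase, had a ratio of 2.46, and Mrc1, the mannose receptor, had 12.7 and 43.3 CPM (ratio 3.42, interval 1.75 to 7.20).

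The 12 genes highest in treated phagocyte-like barcodes were Cd209a, Hist1h1b, Ifitm1, Naaa, Hist1h2ae, Cd74, H2-Ab1, Wdfy4, H2-Aa, Ccnd1, Cbfa2t3 and Fbxo32. Cd209a, a lectin of dendritic cells, had 4.22 and 107 CPM (ratio 25.4, interval 9.60 to 95.2), carried by few barcodes, since at most 8 of 191 PBS and 15 of 119 treated barcodes had a UMI of it or of Flt3. Naaa had 12.7 and 94.6 CPM, and Wdfy4, which dendritic cells use in cross-presentation, had 10.5 and 61.5 CPM. The proliferation list was higher in 13 of 16 members (median 0.63, percentile 99.98), with Top2a at 56.9 and 152 CPM and Mcm2 at 8.43 and 30.8 CPM. Its median was -0.08 when each barcode had the same weight.

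The 12 genes lowest in them were Retnlg, Ccl5, Acod1, Slc4a1, S100a9, Dmp1, Hcar2, G0s2, S100a8, Wfdc21, Mmp9 and Pglyrp1. For most of these the remaining PBS barcodes held about as much, such as Retnlg with 578 CPM in the class and 625 CPM in the remaining barcodes. The treated class carried neutrophil RNA above its background: the neutrophil markers summed to 1889 CPM against 309 CPM in the remaining treated barcodes, and to 9871 against 11394 CPM in the PBS library. With free RNA subtracted, S100a9 was at 0 CPM in the PBS class and 1668 CPM in the treated class, and S100a8 at 0 and 1441 CPM. A value of 0 here means a level at or below the free RNA estimate, not a measured absence. The direction of these 2 genes therefore depends on the subtraction. Of the 12, 2 stood clear of the remaining PBS barcodes. Ccl5, a chemokine, had 85.4 CPM against 5.82 CPM in the remaining PBS barcodes, and 0 UMIs in the treated class, a ratio of at most 0.0504 by its interval. Dmp1, a matrix protein of osteocytes, had 78.0 CPM against 16.3 CPM, and 5.70 CPM in the treated class. Inflammatory secreted factors were lower in 8 of 11 members (median -0.55), with Cxcl2 at 617 and 224 CPM (ratio 0.364, interval 0.308 to 0.428). Interferon-response genes were lower in 9 of 13 members (median -1.03), with Mx1 at 23.2 and 2.28 CPM (ratio 0.0983, interval 0.0112 to 0.3997). Glycolysis and hypoxia genes (median -0.24), senescence genes (median -0.08) and dissociation-stress genes (median 0.21) differed less.

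Neutrophil-like barcodes were too few in the treated library (33) for expression to be compared, so the granule and maturity lists have no value.

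In endothelial-like barcodes the angiogenic list had 8 of 13 members higher in the treated library (median 0.26, interval -0.49 to 0.47, percentile 98.9), and the median was above 0 in 12 of 15 alternatives (-0.11 to 0.9984). Plvap, the diaphragm protein of fenestrated vessels, had 205 and 314 CPM (ratio 1.53, interval 1.36 to 1.71), and Pecam1, a junction protein, had 211 and 282 CPM (ratio 1.34). Esm1, a marker of sprouting tip cells, was lower, with 38.1 and 14.3 CPM (ratio 0.374, interval 0.256 to 0.541). Of the 6 highest genes, Pcdh17 (39.6 and 111 CPM, ratio 2.79, interval 2.19 to 3.60) and Arhgap29 (59.1 and 136 CPM, ratio 2.29) stood above the remaining barcodes, which held 3.17 and 33.4 CPM in the PBS library. Slpi, Mmp13, Lbp and Ibsp were no higher in PBS endothelial-like than in remaining PBS barcodes. The 6 lowest, Retnlg, Slc4a1, Mmp8, Acod1, S100a9 and Ifitm6, were blood transcripts that the remaining PBS barcodes also held at somewhat lower levels, such as Mmp8 at 68.9 CPM against 55.6 CPM and S100a9 at 6683 CPM against 5402 CPM.

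BMP-SMAD targets were higher in 11 of 14 measured members in endothelial-like barcodes (median 0.15, percentile 79.8), but the median was -0.80 with free RNA subtracted. Smad7 had 144 and 237 CPM (ratio 1.64) and Id4 had 6.84 and 16.6 CPM (ratio 2.42, interval 1.33 to 4.71), but the remaining barcodes held as much, with 160 and 251 CPM of Smad7 and 8.56 and 17.5 CPM of Id4. With free RNA subtracted, Smad7 had 141 and 259 CPM (ratio 1.84), against the negative list median. Id4 then had 0.782 and 19.4 CPM. Its ratio of 24.8 stands on a small PBS residue of 14 UMIs and cannot be read as a fold. Proliferation genes were lower in 12 of 16 members (median -0.48), with Mki67 at 61.1 and 29.7 CPM and Mcm3 at 23.0 and 11.6 CPM, against 54.3 and 23.1 CPM and 11.7 and 8.28 CPM in the remaining barcodes. Dissociation-stress genes were higher in 12 of 12 (median 0.32), and interferon-response genes were lower in 9 of 12 (median -0.32). In the 2000 deepest barcodes of each library the proliferation and interferon medians turned to 0.11 and 0.58. Csf1 had ratios of 1.17 in endothelial-like, 1.56 in phagocyte-like and 0.978 in mural-like barcodes, each with an interval that included 1. Bmp2 had ratios of 1.41 (interval 1.14 to 1.75), 0.924 and 1.01 in the same 3 classes, but its 61.6 and 86.7 CPM in endothelial-like barcodes lay below the 96.9 and 88.1 CPM of the remaining barcodes, and Csf1r stood at or below 3.91 CPM in endothelial-like and mural-like barcodes.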

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

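Settings over other barcodes (the deepest, free RNA subtracted, remaining, stromal-like or all kept barcodes, and no clusters with ribosomal-RNA-overlapping transcripts among their top genes) were chosen after seeing the data, as were the list medians led with and the genes printed. A value counts as reversed when its interval excluded no difference and the alternative lay on the other side. That interval covers counting error for shares and gene ratios, and the spread among members for list medians. The neutrophil-like and mononuclear phagocyte-like share ratios stayed below 1 in all alternatives run (0.00922 to 0.141, and 0.362 to 0.662). None of these alternatives removed free RNA before barcodes were assigned to classes. The neutrophil-like ratio may therefore partly be that of free RNA, and its steady side does not settle a difference in cells. The BMP-SMAD median in the skeletal class stayed above 0 in 18 alternatives (0.21 to 0.81), and the MHC class II median in 13 (1.22 to 2.01). Of 499 alternative values of the 32 list medians, 11 reversed and 51 moved beyond their interval. Of 1529 values of the 115 gene ratios chosen for printing, 30 reversed (1.96%) and 547 moved, and 96 of the 115 differed by over 1.5 times from the main value in at least 1 setting. Of 832 values of the 61 gene ratios named by the rule but not chosen, 108 reversed (12.98%) and 257 moved, so the genes chosen overstate stability. Col10a1 of the skeletal class counts among these 61. 30 of those 61 reversed at least once, most often Ebf1, Prrx1, Tagln, Acta2, Fabp4 and Fn1 in the skeletal class. Over all 176, 138 of 2361 values reversed (5.845%). Genes and lists below are of the skeletal class unless another is named, share values are ratios, and the cause was not tested for any of them. With at most 5% mitochondrial UMIs, the mural share was 1.25, the skeletal share 1.83 and the chondrogenic median -0.42, with ratios of 0.960 for Nr4a3, 1.499 for Csf1, 0.560 for Bmp2, 0.779 for Col2a1 and 0.856 for Col9a2. With at most 20%, the mural share was 1.202, the skeletal share 3.25, the chondrogenic median -0.17 and the glycolysis median 0.34, with 0.921 for Nr4a3, 1.16 for Csf1, 0.653 for Bmp2 and 0.954 for Col2a1. With doublets kept, the neutrophil share was 0.0146, the mural share 1.05, the skeletal share 1.17 and Csf1 1.497. At Leiden resolution 0.5, shares were 0.00922 for neutrophil, 0.557 for endothelial, 1.2 for mural, 0.362 for phagocyte and 11.8 for skeletal barcodes, with a glycolysis median of 0.17, an endothelial angiogenic median of 0.9984, and with Csf1r at 2.52 and Col1a1 at 0.9775. At resolution 2.0, shares were 1.75 for endothelial, 0.814 for mural and 1.11 for skeletal barcodes, with Csf1 at 1.445, Bmp2 at 0.882 and endothelial Pecam1 at 0.979. With each library clustered on its own, shares were 0.141 for neutrophil, 0.891 for mural and 1.05 for skeletal barcodes, with Csf1 at 1.25 and Bmp2 at 0.772. Among non-neutrophil barcodes the skeletal share was 3.90. With the mean over barcodes of CPM, the phagocyte proliferation median was -0.0759 and the glycolysis median 0.007655. Thinned to 1000 UMIs, phagocyte Hist1h2ae was 0.802. With equal cluster weights, the chondrogenic median was -0.00639 and the interferon median -0.41, with Csf1 at 1.42, Mki67 at 1.07, Ube2c at 1.10 and Fos at 0.858. In the 2000 deepest barcodes, shares were 0.330 for mural, 0.447 for phagocyte and 3.85 for skeletal barcodes, with the MHC class II median at 2.01 and phagocyte Apoe at 1.85. With free RNA subtracted, the phagocyte dissociation-stress median was -0.05118. In all remaining barcodes, the glycolysis median was 0.01484, Csf1 1.198 and Bmp2 0.909. In the stromal-like clusters, the chondrogenic median was -0.17, Csf1 1.49, Bmp2 0.687 and Col2a1 0.961. In all kept barcodes, the glycolysis median was 0.04873, Csf1 1.05 and Bmp2 0.947. A minimum of 1000 UMIs removed no barcode, so it tests nothing, and equal weights changed only the skeletal class, through clusters 8 and 13. The values at that minimum are still counted among the alternatives above, which makes the shares that reversed look lower. The changes of scaling are counted too, although they multiply all gene ratios of a class by the same factor. In the mural class free RNA subtraction left 1.98% of PBS RNA, with Id1 at or below the free RNA estimate, and gave ratios of 0.562 for Bmp2 and 0.774 for Csf1. Medians whose interval included 0 are not counted as reversed, and 15 of the 32 list medians changed sign without being counted. With at most 5% mitochondrial UMIs and at Leiden resolution 0.5 the phagocyte class held 91 and 63 treated barcodes, too few for expression to be compared. Barcode numbers limit the precision in the phagocyte class (191 and 119) and left too few treated neutrophil-like barcodes (33) for expression.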

Other observations

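Some single clusters held barcodes of both libraries. Cluster 8, part of the skeletal stromal class, was led by Mmp13, the collagenase of hypertrophic cartilage, with Col10a1, the collagen of the same cells, and Spp1 and Fam20c, which belong to mineralising matrix. It held 93 PBS barcodes (1.04%, interval 0.838 to 1.27%) and 302 treated barcodes (3.50%, interval 3.13 to 3.91%). Cluster 13, of the same class, was led by the mitosis genes Top2a, Mki67 and Cenpf and carried 4 stromal markers, with 50 PBS barcodes (0.557%) and 106 treated ones (1.23%). Cluster 7 was led by Mpo, Prtn3, Ctsg and Elane, granule proteases of immature myeloid cells, with 51 PBS barcodes and 1 treated barcode. As with all clusters of these libraries, their sizes have no replicate check.

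Most clusters found almost wholly in 1 library paired up across the libraries by their leading genes. Cluster 0 (1121 PBS barcodes) and cluster 11 (962 treated barcodes) shared 38 of their top 50 genes, among them Espn, Ero1l, Cdsn, Mt2 and Apln. Clusters 2 and 12 shared 26, and clusters 3 and 14 shared 24. Clusters 3 and 14, which both had Mir6236 and Gm42418, transcripts that overlap ribosomal RNA, among their top 10 genes, held 28.2% and 29.7% of the kept barcodes. Ibsp was higher in the treated cluster of each of the 4 pairs, for example at 4608 CPM in cluster 5 and 11513 CPM in cluster 15. PBS cluster 1 (346 barcodes) shared at most 6 top genes with a treated cluster and was left unpaired. Its Ibsp, at 11736 CPM, lay above treated clusters 11 (5154 CPM), 12 (10639 CPM) and 15, and below cluster 14 (13114 CPM).

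The tests of 3 patterns follow. The test over matched cluster pairs was set out before its result was seen, and the others after.

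Neutrophil and haemoglobin RNA was far higher in the PBS library. Free RNA in every barcode may account for its presence outside the neutrophil-like cluster: S100a8 differed only 1.82-fold from the lowest to the highest of 8 other PBS clusters, and S100a9 stood in a steady ratio to it, from 1.53 to 1.67. Why the PBS library held more of it was not tested: more blood or marrow RNA of all kinds in that suspension and fewer neutrophils in the treated callus both stay open, because each condition has a single library.

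BMP-SMAD target genes were higher in the treated library. Different clusters behind the skeletal class in each library are argued against as the whole cause. The list median was above 0 in 4 of 4 matched cluster pairs, from 0.27 to 0.49, of which only clusters 5 and 15 (0.45) lie wholly within the class. The 4 pairs are not separate evidence, since they come from the same 2 libraries and all kept barcodes had a median of 0.37. Matching added little: of clusters sharing 0 top genes, 5 and 14 had 0.68, but 2 and 15 had -0.002. A stress response during dissociation stays open, since the list median exceeded the stress median in 2 of 4 pairs, although in the stromal-like clusters it was 0.50 against 0.17. Free RNA that differs between the libraries stays open for part of it, because the list also had a median of 0.28 in phagocyte-, endothelial- and mural-like barcodes together, where a response of those cells cannot be told apart from free RNA, and the weakest pair was no higher. The BMP2 in the hydrogel remains a candidate explanation, untested for want of replicate libraries.

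MHC class II genes were higher and C1q genes lower in treated phagocyte-like barcodes. Less free RNA in the treated barcodes would raise both, but the summed C1q level had a ratio of 0.348 (interval 0.303 to 0.399). The lower C1q is part of the pattern and was known beforehand, so this speaks only to C1q and not to the MHC class II rise. With free RNA subtracted, the ratios were 2.45 for Cd74, 2.58 for H2-Ab1 and 2.07 for H2-Aa. Each was smaller than before subtraction but still higher in the treated library, so less free RNA may account for part of that rise. Within barcodes with at least 2 C1q UMIs (95 PBS and 30 treated), the summed MHC class II ratio was 0.762 (interval 0.698 to 0.830), while it was 6.14 in the others (96 and 89), and 8 of 191 and 15 of 119 barcodes had a Cd209a or Flt3 UMI. Because this split uses genes of the pattern itself, at unequal depths, it decides nothing between a different mix of cells and macrophages that held less C1q and more MHC class II. Both stay open, as does whether the anti-CSF1 antibody, BMP2 or the sampling set the difference.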
